A study of Mus musculus with 2 samples.

How the data were processed

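The series holds 2 single-cell libraries, prepared with the 10x Chromium 3′ kit, version 3, from mouse skin of strain C57BL/6;CD1. The cells are hair follicle stem cells sorted by fluorescence for the surface protein CD34 and for a green fluorescent histone driven by the keratin 14 promoter. Both libraries are labelled as replicates of 1 group: wild type, anagen (the growth phase of the hair cycle), postnatal day 32. There is no second group, so no treatment or genotype was compared. Whether each library came from its own animal, the number of animals, their sex and the sequencing dates are not given in the sources used here.

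The deposited matrices hold counts: UMI counts, whole numbers of unique molecular identifiers per gene and cell barcode, with no normalization. According to the submitters' processing notes, reads were processed with Cell Ranger 3.1.0 against mm10 and analysed with Seurat 3.1; the matrices hold the values from before that later step. The gene models used are not given in the sources used here. Of the 31053 features, 30934 were found by identifier in GENCODE M21 (GRCm38), from which coordinates were taken. No feature is named for the fluorescent reporter. Single-cell reads without a mapped UMI, cell labels and clusters of the original work were not used here.

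Replicate 1 has 6592 barcodes and 52344178 UMIs, with a median of 7432 UMIs and 2309 genes per barcode. Replicate 2 has 5080 barcodes and 38678103 UMIs, with medians of 6733.5 and 2232. Cells were kept with at least 1000 detected genes and at most 10% of UMIs from mitochondrial genes. The gene minimum removed 1587 barcodes of replicate 1 and 1543 of replicate 2, and the mitochondrial limit removed a further 1087 and 496. Doublets were scored per library with Scrublet, as in scanpy 1.11.5, on cells with at least 500 genes and at most 20% mitochondrial UMIs. The automatic threshold called 0 cells in each library, so the fallback set beforehand was used: the highest-scoring share of cells, 0.8% for every 1000 barcodes of the library. It called 255 and 139 cells, of which 214 and 131 had passed the other filters and were removed. Doublets between cells of like state are not found by such scores. After filtering, 3704 cells of replicate 1 remained, with 1723 to 66975 UMIs per cell, and 2910 of replicate 2, with 1951 to 97873. RNA free in the droplets was not removed, since empty droplets were not analysed here.

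Each UMI count was split at random with probability 0.5 (seed 1). One part served for clustering, so that the same counts did not both form and test a cluster. The held-out part served for every test and CPM level and for naming and classing the clusters. The printed detection shares and shares of cells with at least 3 cycling markers used all UMIs of each cell, before or after thinning. They therefore include the part that formed the clusters. For clustering, counts per 10000 were log-transformed. The 2000 most variable genes were chosen by analytic Pearson residuals with theta 100, by mean rank over the libraries, without mitochondrial genes, Xist, Tsix and Y-linked genes. Genes were centred and scaled within each library and reduced to 30 principal components, and Leiden clustering (leidenalg 0.10.2) was run at resolution 0.5 on a shared-neighbour graph of 20 neighbours. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0.

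Clusters were named from marker lists fixed before the data were examined, as were the filters, main comparisons, gene lists, naming rules and most alternatives. The comparisons of each cycling cluster with its nearest non-cycling cluster and of cluster 2 with cluster 4 were chosen after the clusters were seen. The rule that sorts clusters into classes was revised after the clusters were seen. A cluster is counted as other cell types where Krt5 and Krt14 together stay under 500 CPM (UMIs scaled to a common total) or where at least 3 of its 10 leading genes are markers of a cell type other than keratinocytes. Of the rest, it is cycling where at least 3 leading genes are cycling markers, mixed where over 50% of its cells in either library detect at least 3 cycling markers without such leading genes, and non-cycling otherwise. A name ending in -like rests on at least 3 detected markers of the fixed lists. Detection is the share of cells with at least 1 UMI, given as found and after thinning each cell to 5000 UMIs; shares carry exact 95% Clopper-Pearson intervals. Intervals and floors cover counting error only, where a count of 0 allows up to 3 counts.

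Held-out UMIs were summed per cluster and library for the 11 clusters with at least 20 cells in both libraries, which gave 22 sums. The sums were fitted with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, two-sided, with TMM normalization, the edgeR expression filter, a coefficient per cluster and a term for the library. The fit had 12 coefficients, 10 residual degrees of freedom and 10423 genes. The 2 cycling clusters were compared with the 7 non-cycling clusters, each non-cycling cluster with the mean of the other non-cycling clusters, all non-cycling clusters jointly, and each cycling cluster with its nearest non-cycling cluster. That nearest cluster was found by correlation across variable genes without the cell cycle genes. Reference levels in the fit are means of log levels, so 1 cluster at 0 lowers them. The printed CPM levels are arithmetic means over clusters, then over libraries. Each SE is the absolute log2 fold change divided by the square root of F, and is left empty where F is near 0. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, called at 0.05. The same clusters appear in every comparison, and the residual degrees of freedom rest on clusters within 2 libraries. The p-values therefore measure only the spread between these samples, which may be technical, and not the spread between animals. Cells were never used as replicates. Of the genes picked by the fixed rule, 2 are not reported here; they stayed in every fit and list.

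The 24 fixed gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Each list needed at least 5 tested genes, and S phase and G2/M genes were left out of the other lists. Adjustment was over all lists of the cluster comparisons, or over the lists of 1 comparison for the others. The list names are S phase, G2/M phase, bulge stem cell identity, quiescence and BMP response, WNT response, hedgehog response, Notch response, hemidesmosome and basement membrane, secreted and adhesion matrix, actin and contractility, TGF-beta and YAP targets, immediate early genes, heat shock, epidermal differentiation, stratified keratins, cytosolic ribosomal proteins, ribosome biogenesis and MYC targets, oxidative phosphorylation, glycolysis, cholesterol and lipid synthesis, p53 targets and apoptosis, interferon response and antigen presentation, upper hair follicle, and hair germ and lower outer root sheath. Atp5o and Aldoa were not found among the features. Some lists share genes, so their calls are not fully separate results. Btg2 is in the quiescence and immediate early lists, and Smad7 in the quiescence and TGF-beta lists. Cyr61 is in the immediate early and TGF-beta lists, and Klf4 in the immediate early and epidermal differentiation lists.

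Genes were named by rule. For cycling cells these were the 8 largest increases and 8 largest decreases among called genes with at least 50 CPM in the higher class and the same sign in both libraries, without predicted genes and, among the increases, without the cell cycle lists. The 4 genes with the smallest p of each cell cycle list were added. Each non-cycling cluster gave its 4 largest increases and 3 largest decreases, and each called list its 3 members with the smallest p. Cd34, Krt14, Krt5, Krt15, Lgr5 and Mki67 were always kept. A subset of these is printed. A gene with 0 UMIs on one side is given as at least a fold, against a floor of 3 counts over the group. A gene with 1 to 3 UMIs on one side is given as a ratio with its 95% counting interval.

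The fit was tested on simulated data of the same depth and design with 9815 genes. It recovered 97% of genes changed by log2 1 and 100% of those changed by log2 2, with 7 false calls. Changes were placed only in genes with a mean above 20 CPM. Genes were drawn independently, and the simulated clusters differed in nothing else. These shares therefore do not measure recovery over all tested genes of the real data. Alternatives were each library left out, no library term, DESeq2 1.42.0, RLE normalization (which moved the median of all genes by log2 0.03), no expression filter, all UMIs in place of the held-out part, another split, mitochondrial limits of 5% and 20%, gene minimums of 500 and 2000, doublets kept, resolutions of 0.3 and 0.8, 1000 and 4000 variable genes for the separate clustering, no centring within libraries, cycling cells called by markers with or without cell cycle genes in the clustering, the 2 classes summed per library, and the joint test on genes outside the variable genes. More were chosen after seeing the data and are named with their values in the closing section.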

Results

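Krt14, the keratin whose promoter drives the sorted reporter, was detected in 97.5% of the keratinocytes kept from replicate 1 and in 97.7% of those from replicate 2. Krt5, its partner in basal keratinocytes, was detected in 99.8% of them in each library. Clusters were counted as keratinocytes partly by their Krt5 and Krt14 levels, so these shares do not test the sort. Joint clustering of the 3704 and 2910 kept cells gave 13 clusters, of which 7 were non-cycling keratinocytes, 2 cycling keratinocytes, 2 mixed and 2 other cell types. Of the kept cells, 79.0% in replicate 1 and 68.9% in replicate 2 were in non-cycling clusters (mean 73.9% ± 7.16, SD, n = 2 libraries). Cells of other types made up 2.05% (95% interval 1.62 to 2.56) and 1.92% (1.46 to 2.49). The mixed clusters held 2.73% and 21.2%, of which cluster 6 made up 0.864% and 19.3% of the cells and cluster 10 1.86% and 1.89%. All values come from 2 libraries of 1 group, and nothing in the labels says that they come from separate animals.

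Cluster 1 was led by Pthlh, Wfdc18 and Sbsn, clusters 2 and 4 by Tagln and Edn2, cluster 3 by Gnmt, Nppc and Fst, and cluster 5 by Tagln, Acta2 and Fgf5. Cluster 9 was led by Calml3, Krt24 and Tgm5. It was bulge stem cell-like, with 13 of 15 bulge markers at 20 CPM or more and 6 of them at their highest level of all clusters, although Calml3 and Dmkn among its leading genes belong to the epidermal differentiation list. Cluster 12, led by Defb6, Cst6, Ly6d and Krt79, was upper hair follicle-like, with 6 of 9 markers highest there. It also had the highest level of 4 of 7 sebaceous gland markers. These genes describe the clusters and were used to name them. Cluster 1 held 26.9% of replicate 1 and 12.9% of replicate 2, cluster 2 20.7% and 17.8%, cluster 3 10.7% and 9.59%, cluster 4 11.3% and 7.39%, and cluster 5 7.59% and 11.4%. Cluster 9 held 1.19% (95% interval 0.864 to 1.59) and 8.63% (7.63 to 9.70), so that 85.1% of its 295 cells came from replicate 2. Cluster 12 held 0.621% and 1.20%, or 23 and 35 cells.

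Cluster 6, a mixed cluster led by Sms, Hist1h2ae, Krtdap and Sostdc1, held 0.864% of replicate 1 and 19.3% of replicate 2, and 94.6% of its cells came from replicate 2. Its median depth was 15517 UMIs per cell. At least 3 cycling markers were detected in 81.3% of its 32 cells in replicate 1 and in 72.1% of its 563 in replicate 2. After thinning, the shares were 80.0% and 56.7%. Mki67, a marker of dividing cells, averaged 252 ± 99.2 CPM there (SD, n = 2 libraries). Cluster 10 was inner root sheath-like, with Krt25, Krt71, Krt28 and Krt27 in the lead and 6 of 7 inner root sheath markers highest there. It also had the highest level of 4 of 7 hair matrix markers. It held 1.86% and 1.89% of cells at the greatest median depth of all clusters, 19180.5 UMIs. Krt71 reached 1914 CPM in replicate 1 and 113 CPM in replicate 2 in that cluster, and Krt25 1606 and 213 CPM.

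**Figure D1:**
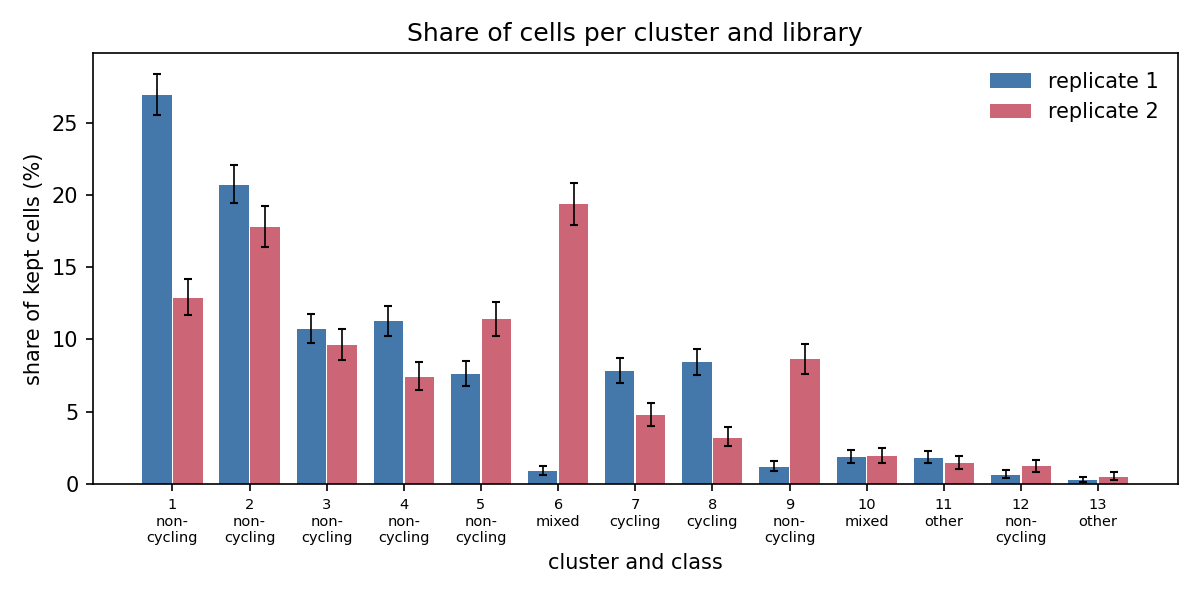
Share of kept cells (%) in each cluster, one bar per library with its exact 95% Clopper-Pearson interval, which covers counting error only. Clusters 6 and 9 lie mostly in replicate 2, and cluster 1 takes 26.9% of replicate 1 and 12.9% of replicate 2.

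Cd34, the transcript of the surface protein used in the sort, had at least 1 UMI in 29.1% of keratinocytes of replicate 1 (95% interval 27.5 to 30.6) and 33.0% of replicate 2 (31.3 to 34.9), after thinning to 5000 UMIs. Unthinned, the shares were 45.4% and 46.8% at median depths of 9712.5 and 9575.5 UMIs. Cluster 9 had the highest thinned shares among keratinocytes, 52.4% and 74.8%, followed by cluster 4 with 47.8% and 50% and cluster 2 with 44.0% and 41.5%. Clusters 1 and 8 had 12.5% to 14.0%. In the upper hair follicle-like cluster 12, 0 of 22 and 0 of 34 thinned cells had a Cd34 UMI, which allows shares of cells with a UMI of up to 13.6% and 8.82%. The immune cells of cluster 13, which serve as a type that should lack most follicle transcripts, gave 0 of 9 and 0 of 14, allowing up to 33.3% and 21.4%, at a pooled median of 11143 UMIs. Unthinned, Cd34 was found in 0% and 2.86% of the cells of cluster 12 and in 11.1% (1 of 9 cells) and 0% of those of cluster 13. Fibroblast-like cluster 11 had Cd34 in 78.3% and 64.1% of thinned cells, above every keratinocyte cluster in replicate 1 and below cluster 9 in replicate 2; fibroblasts are known to express this gene. Lgr5, a stem cell receptor gene, was detected in 34.7% and 42.4% of thinned keratinocytes against 2.90% and 1.89% of thinned other cells. Krt14 was detected in 95.8% and 96.4% of thinned keratinocytes and in 23.2% and 18.9% of thinned other cells. The unthinned median depths of the other cells were 11741.5 and 13567 UMIs. Unthinned, 38.2% and 37.5% of other cells had a Krt14 UMI. The groups were divided partly by their Krt5 and Krt14 levels, so this difference is partly built into them.

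Cluster 11 was named from Col3a1, Col1a1 and Col1a2, with all 6 fibroblast markers at their highest level there. Col1a1 averaged 9538 ± 605 CPM in it (SD, n = 2 libraries) and stayed between 2.46 and 5.46 CPM in clusters 1 to 10. All 5 endothelial markers were also highest in cluster 11, among them Pecam1 at 73.7 ± 77.4 CPM, so it pools more than 1 cell type. Cluster 13 had the highest level of all 6 dendritic cell and all 6 macrophage markers, with Cd74 at 28802 ± 979 CPM and Lyz2 at 9974 ± 3239 CPM. It held 9 and 14 cells.

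**Figure D2:**
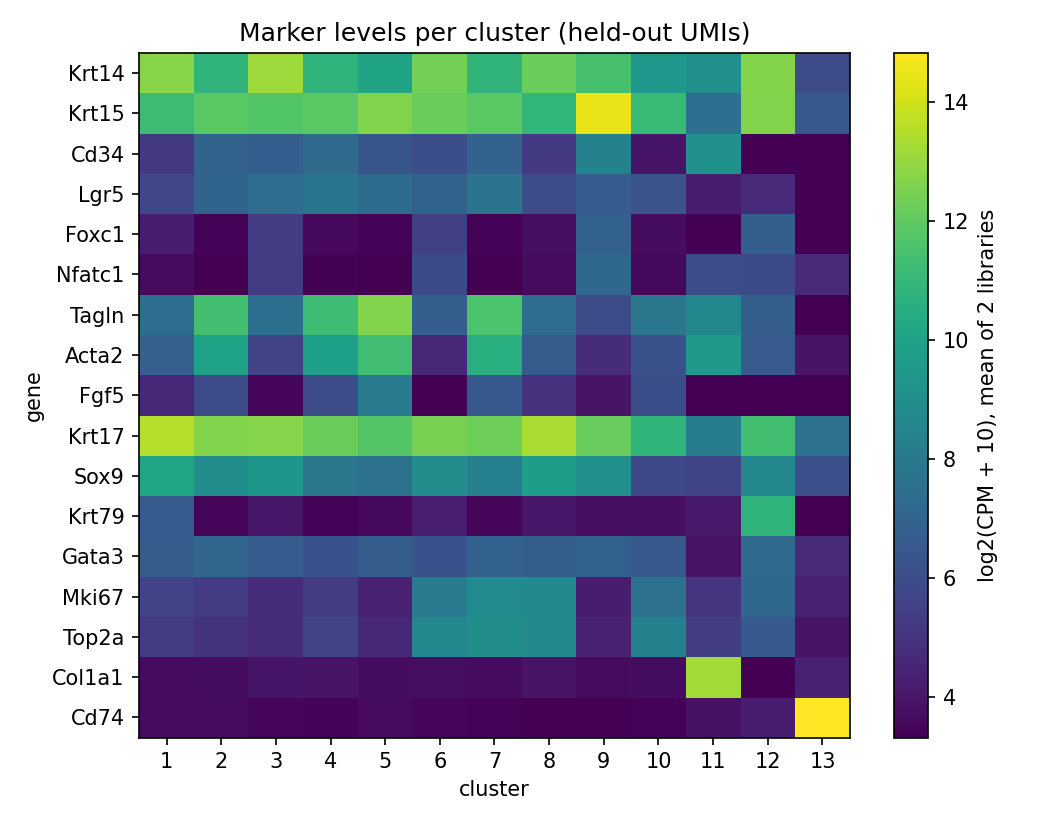
Heat map of log2(CPM + 10) for 17 genes (rows) in clusters 1 to 13 (columns), mean of 2 libraries. Cd34 is highest in cluster 9 among keratinocytes, and Col1a1 and Cd74 stand out in clusters 11 and 13.

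Cycling keratinocytes, which were clusters 7 and 8, had a far higher level of genes of mitosis than non-cycling keratinocytes. Among genes outside the cell cycle lists, Cep55, which acts in the last step of cell separation, reached 53.3 ± 3.0 CPM against 1.65 ± 0.356 (SD, n = 2 libraries), and Plk1, a mitotic kinase, 85.4 ± 0.348 against 2.15 ± 1.31. Ccna2, a cyclin of S phase and mitosis, averaged 136 ± 5.89 against 6.27 ± 4.46 CPM, with Kif22, Depdc1a and Aspm changed by a like factor. The replication histone gene Hist1h2ae averaged 335 ± 408 CPM, so that its level differed widely between the libraries; histone genes of this family share much of their sequence. Fitted log2 fold changes were 5.97 ± 0.34 (SE) for Cep55, 5.85 ± 0.24 for Plk1 and 5.58 ± 0.22 for Ccna2, each higher in both libraries. Their adjusted p-values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided, were 1.23e-13, 3.88e-17 and 2.21e-17. From the fixed cell cycle lists, Ube2c averaged 579 ± 38.6 against 20.8 ± 4.87 CPM (log2 5.20 ± 0.13), Cdca8 changed by log2 4.53 ± 0.13, Hmmr by 5.74 ± 0.18 and Mki67 by 3.94 ± 0.15. S phase genes changed less: Tyms averaged 221 ± 38 against 51.3 ± 6.07 CPM (log2 2.28 ± 0.11), Rrm1 changed by log2 1.96 ± 0.13 and Rrm2 by 2.40 ± 0.17. In all, 1435 genes were higher and 1245 lower of 10423 tested. The cycling clusters were picked partly by 12 cycling markers, read in the same held-out UMIs that were tested. The increases in the cell cycle lists and in other genes of mitosis, such as Cep55, Plk1 and Ccna2, therefore describe these clusters. Their p-values add no independent support for the class.

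Col17a1, Krt15 and Dap were lower in the cycling clusters than in the mean of the non-cycling clusters. Col17a1, a collagen that anchors basal cells to the basement membrane, averaged 74.9 ± 10.1 CPM in cycling and 323 ± 30.9 CPM in non-cycling clusters (SD, n = 2 libraries), a log2 fold change of -2.13 ± 0.17 (SE). Krt15, a keratin gene of bulge cells, averaged 2628 ± 373 against 7159 ± 1538 CPM (log2 -1.10 ± 0.12), and Dap 7.05 ± 0.470 against 64.9 ± 0.646 CPM (log2 -2.43 ± 0.27). The adjusted p-values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided, were 8.19e-11 for Col17a1, 4.43e-08 for Krt15 and 6.80e-08 for Dap, each lower in both libraries. Col17a1 and Krt15 were also lower in non-cycling cluster 1, the nearest to cycling cluster 8, than in the other non-cycling clusters. The non-cycling level of Krt15 includes cluster 9, where it was higher. The contrast therefore does not separate cycling from state for Col17a1 and Krt15. Tgfbi, Fam25c, Cst6 and Aqp3 changed by log2 -2.27 ± 0.41, -2.81 ± 0.67, -2.45 ± 0.44 and -2.38 ± 0.84. Of the genes with 1 to 3 UMIs in cycling cells, Defb6 was lower by a ratio of 62.9 (95% counting interval 21.4 to 305), Calm4 by 36.9 (10.1 to 306) and Stfa3 by 30.1 (8.26 to 250). Part of these decreases rests on cluster 12 alone: Defb6 averaged 2121 ± 1149 CPM there and 5.18 ± 5.96 in the other non-cycling clusters. Calm4 and Aqp3 changed sign, to log2 0.90 and 0.50, when clusters were drawn at resolution 0.3, where the only cycling cluster was led by Krt25, Krt71 and Krt28 and none was matched to cluster 8. Without cluster 12 they were -1.65 and -1.63, no longer called. Cd34 changed by log2 0.44 ± 0.69, Lgr5 by 0.16 ± 0.14 and Krt14 by -0.33 ± 0.16, none of them called, and Krt5 by -0.36 ± 0.11, which was called.

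Of the fixed lists, all 54 G2/M phase genes tested were higher in cycling cells, and 36 of 43 S phase genes (37 adjusted over the list alone, with 1 lower). The G2/M list had a median log2 fold change of 4.24 and the S phase list 1.28. All 44 cytosolic ribosomal protein genes were lower, as they were adjusted over the list alone, with a median of -0.63; Rpl5 averaged 1234 ± 26.3 against 2189 ± 159 CPM (SD, n = 2 libraries), a log2 fold change of -0.82 ± 0.09 (SE), and Rpl13 and Rpl34 changed by -0.73 ± 0.08 and -0.72 ± 0.08. Many ribosomal protein genes share reads with pseudogenes. Hemidesmosome and basement membrane genes were mostly lower, with a median of -0.62. Of 19, 11 were lower and 1 higher (13 and 1 adjusted over the list alone). Dst changed by log2 -0.91 ± 0.11 and Lamb3 by -1.33 ± 0.17. Non-cycling cluster 1, the nearest to cycling cluster 8, had a median of -1.23 for this list against the other non-cycling clusters. The contrast therefore does not separate cycling from state for these genes. Cholesterol and lipid synthesis genes were mostly higher, 14 of 24 against 1 lower (the same counts adjusted over the list alone), with a median of 0.50 and with Cyp51 at log2 1.04 ± 0.14 and Fdps at 0.94 ± 0.11. Lower medians were also called for TGF-beta and YAP targets (-0.22; Crim1 -0.74, Cyr61 -0.83), immediate early genes (-0.25; Myc -1.08, Fosb -0.67) and glycolysis (-0.42; Gpi1 -0.65, Pfkp -0.57), with 6 of 15, 11 of 22 and 9 of 16 genes lower and the same counts adjusted over the list alone. Camera called 8 of 24 lists at the preset correlation. Only the G2/M list held with an estimated correlation, with an adjusted p = 9.94e-05 with an estimated correlation against 0.112 for S phase, 0.112 for cholesterol synthesis, 0.223 for hemidesmosome and 0.269 for ribosomal protein genes.

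The other 16 lists were not called between cycling and non-cycling cells. Their median log2 fold changes were -0.24 for bulge identity, -0.48 for quiescence and BMP response, -0.20 for WNT response, -0.16 for hedgehog response, 0.27 for Notch response, -0.44 for secreted matrix and 0.32 for actin. They were -0.32 for heat shock, -0.71 for epidermal differentiation, -0.53 for stratified keratins, -0.08 for ribosome biogenesis, 0.05 for oxidative phosphorylation and -0.24 for p53 targets. Interferon response had a median of 0.09 while its test pointed down; upper hair follicle had -1.78 and hair germ 0.16. Actin genes included 9 of 20 higher and 0 lower, and oxidative phosphorylation genes 11 of 45 higher and 3 lower, in each case with the same counts adjusted over the list alone.

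**Figure D3:**
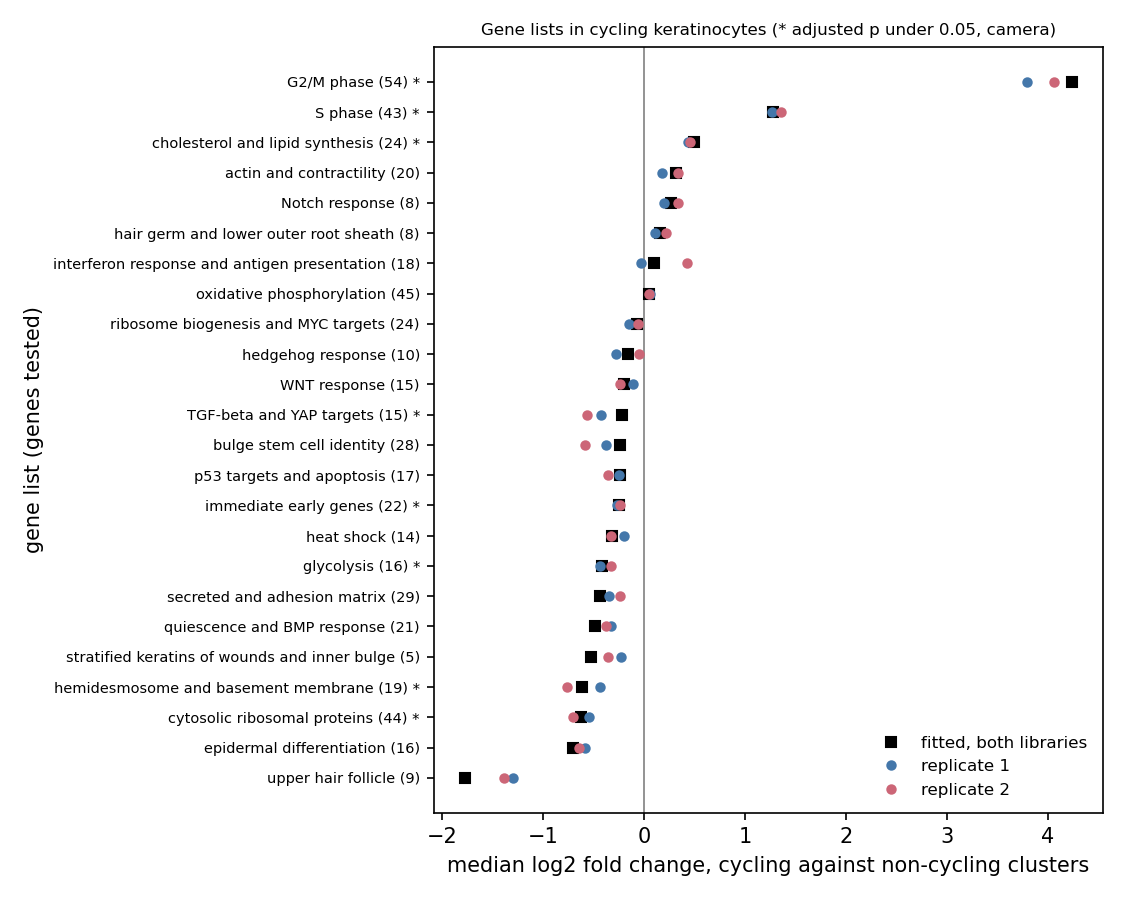
Median log2 fold change of 24 gene lists between cycling and non-cycling keratinocytes, with squares for the fitted value, dots for each library, and stars for lists called by camera at the preset correlation. G2/M genes sit at 4.24 and ribosomal protein genes at -0.63.

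Cluster 7, with Tagln and Acta2 among its leading genes, was closest in its other genes to non-cycling cluster 4, and cluster 8, with Wfdc18 and Pthlh, was closest to cluster 1. Pearson's r across variable genes was 0.64 between clusters 7 and 4, 0.61 between 7 and 2, and 0.78 between 8 and 1; genes are not independent replicates. Against cluster 4, 558 genes were higher and 393 lower in cluster 7. Against cluster 1, 473 were higher and 246 lower in cluster 8. The comparisons shared 345 higher and 96 lower genes, where 25.3 and 9.28 were expected of independent lists. Clusters 7 and 8 were both picked by cycling markers, so shared higher genes of the cell cycle were set by that choice. Both comparisons also come from the same fit. The excess over independent lists is therefore no test of a shared change. Ribosomal protein genes were lower in each, with 36 and 32 of 44 called, medians of -0.53 and -0.52, and 42 and 44 lower adjusted over the list alone. Cholesterol synthesis genes were higher in each, with medians of 0.41 and 0.46, 4 of 24 called in each, and 10 and 8 adjusted over the list alone. Of the immediate early genes, whose transcripts rise within minutes of a stimulus, 18 of 22 were higher in cluster 7 than in cluster 4 (median 1.16), and 0 were called between clusters 8 and 1 (median -0.20); the difference between these changes was not tested for the list. A test of the difference by gene called 75 genes, all of them changed more upward in cluster 7, and 1 gene when cluster 7 was compared with the mean of clusters 2 and 4. Of these lists, none but G2/M held with an estimated correlation.

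The share of cells in cycling clusters was 16.2% in replicate 1 (95% interval 15.1 to 17.5) and 7.97% in replicate 2 (7.01 to 9.02), with a mean of 12.1% ± 5.84 (SD, n = 2 libraries). The mixed clusters held 2.73% of replicate 1 and 21.2% of replicate 2. Counted as cycling, they would put replicate 2 above replicate 1. By markers alone, cells with at least 3 of 12 cycling markers made up 35.7% and 35.3%, and after thinning 27.2% and 28.2%. Fewer cells of cluster 9 passed this count of markers, 0% in each library after thinning, than of any other keratinocyte cluster; in clusters 3 and 5 it was 2.30% to 5.43%, in clusters 1, 2 and 4 10.7% to 19.7%, and in cluster 12 27.3% and 5.88%. The marker counts may also include free RNA, which was neither removed nor measured here.

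Among the 7 non-cycling clusters, 5051 of 10423 genes differed in a joint edgeR quasi-likelihood test. Of the 8817 genes that had not been used to form the clusters, 3487 differed. Each cluster was then compared with the mean of the other 6. That reference is a mean of log levels, which a low cluster pulls down. Fitted increases can therefore exceed the ratios of the printed CPM levels. Cluster 1 had 1249 genes higher and 727 lower, cluster 2 1196 and 488, cluster 3 1387 and 390, cluster 4 1287 and 908, cluster 5 1364 and 871, cluster 9 1073 and 852, and cluster 12 854 and 620.

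Cluster 1 had more Krt17, Sox9 and Krt14 and less Krt15, Lgr5 and Col17a1 than the other non-cycling clusters. Krt17, a keratin gene of the outer root sheath, averaged 12346 ± 1430 against 4948 ± 1197 CPM (SD, n = 2 libraries), a log2 fold change of 1.46 ± 0.19 (SE). Sox9, a follicle transcription factor, averaged 1089 ± 270 against 443 ± 139 CPM (log2 1.48 ± 0.12), and Krt14 changed by log2 1.26 ± 0.18. Col17a1 averaged 18.4 ± 1.70 against 374 ± 36.3 CPM (log2 -3.77 ± 0.22), Krt15 2376 ± 816 against 7956 ± 1659 CPM (log2 -1.40 ± 0.17), and Lgr5 46.0 ± 11.9 against 129 ± 18.0 CPM (log2 -1.15 ± 0.19). The largest increases were Wfdc18 (log2 6.60 ± 0.24), Dclk1 (5.28 ± 0.25), Sytl2 (4.55 ± 0.31) and Bpifc (4.54 ± 0.27). Among the decreases, Prlr changed by -4.37 ± 0.38 and Igfbp3 by -4.11 ± 0.47, and Clca3a2, with 0 UMIs in cluster 1, was at least 27.4-fold lower. Hemidesmosome genes were lower, 15 of 19 (the same adjusted over the list alone; median -1.23), as were secreted matrix genes (13 of 29, also adjusted over the list alone; median -1.38) and TGF-beta and YAP targets (7 of 15, also adjusted over the list alone; median -0.95), with Cyr61 at log2 -1.66 ± 0.22. Notch genes were higher (5 of 8, also adjusted over the list alone; median 0.81), with Notch3 at log2 3.39 ± 0.29, Nrarp at 2.13 ± 0.16 and Notch1 at 1.68 ± 0.15. Epidermal differentiation genes were called higher (5 of 16, or 7 adjusted over the list alone; median 0.13, or -0.017 with clusters and levels from all UMIs), with Sbsn at log2 2.60 ± 0.14. These 5 of 12 called lists held with an estimated correlation. S phase, G2/M, stratified keratin, cholesterol and interferon lists were called higher (medians 0.81, 0.47, 1.60, 0.23 and 0.44) and the bulge and ribosomal protein lists lower (-0.25 and -0.14), without holding. Median and test differed in sign for WNT response (-0.80, or -0.47 with genes at their bounds) and hair germ (-0.13), both with a test pointing up and neither called.

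Cluster 2 had more of the smooth muscle genes Acta2 and Tagln and of Fn1, the fibronectin gene, and less Krt14 and Krt5. Fn1 averaged 192 ± 7.95 against 67.3 ± 9.82 CPM (SD, n = 2 libraries), a log2 fold change of 3.68 ± 0.20 (SE), Acta2 1089 ± 25 against 599 ± 134 CPM (log2 3.02 ± 0.24), and Tagln changed by log2 3.15 ± 0.33. The fitted values of Fn1 and Acta2 exceed the ratios of their levels, since low clusters pull down the reference, a mean of log levels. Btg2, an antiproliferative immediate early gene, averaged 2184 ± 401 against 944 ± 193 CPM (log2 1.34 ± 0.10). Krt5 changed by log2 -0.95 ± 0.16 and Krt14 by -0.91 ± 0.22, which became 0.05 at a mitochondrial limit of 20%. Dio3 (log2 3.95 ± 0.31), Cpxm1 (3.34 ± 0.26) and Ggt1 (3.24 ± 0.31) were the other largest increases. Calml3 (-4.82 ± 0.50) and Anxa8 (-4.38 ± 0.44) were among the largest decreases, with Tmem45a lower by a ratio of 106 (95% counting interval 18.9 to 4208). Secreted matrix genes (16 of 29 higher, median 0.90) and actin genes (13 of 20, or 15 adjusted over the list alone, median 0.80) were higher, as were hair germ genes (4 of 8, or 7 adjusted over the list alone, median 0.63), with Cdh3 at log2 1.09 ± 0.14 and Fgf5 at 3.17 ± 0.34. Epidermal differentiation genes were lower (8 of 16, also adjusted over the list alone, median -1.17), with Sbsn at log2 -2.49 ± 0.20. These 4 of 11 called lists held with an estimated correlation. Immediate early (14 of 22 higher, median 0.82), heat shock (0.29), S phase (0.40), G2/M (0.47) and oxidative phosphorylation (0.15) lists were called higher, and glycolysis (-0.25) and upper hair follicle (-2.40) lower, without holding. With clusters and levels from all UMIs, the medians of immediate early and heat shock genes were -0.024 and -0.083, but there no cluster was matched to cluster 4 and the cluster matched to cluster 2 was a larger set of cells (overlap 0.601, Jaccard index). Median and test differed in sign for TGF-beta and YAP targets (0.04) and stratified keratins (0.46), neither called.

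Cluster 3 had more Fst, Sfrp1, Col17a1 and Krt14, and more of all 22 immediate early genes. Col17a1 averaged 737 ± 9.28 against 254 ± 34.5 CPM (SD, n = 2 libraries), a log2 fold change of 2.41 ± 0.13 (SE), and Krt14 9796 ± 434 against 3675 ± 511 CPM (log2 1.78 ± 0.18). Fst, an inhibitor of activin, averaged 885 ± 612 against 251 ± 61.8 CPM (log2 2.76 ± 0.21) and Sfrp1, a secreted WNT antagonist, 1006 ± 436 against 393 ± 192 CPM (log2 2.25 ± 0.19). Lgr5 changed by log2 1.13 ± 0.15. Gdf10 (log2 6.65 ± 0.40), Scrg1 (5.02 ± 0.30), Nrg1 (4.99 ± 0.26) and Nppc (4.73 ± 0.22) rose most. Krt19 (-2.96 ± 0.52) and Cux1 (-2.40 ± 0.47) fell, and Calm4 was lower by a ratio of 54.5 (95% counting interval 9.72 to 2160). The clusters matched to it at a mitochondrial limit of 20% and at resolution 0.3, where Calm4 was higher (log2 5.10 and 7.68), are other sets of cells, with overlaps (Jaccard index) of only 0.404 and 0.408 with cluster 3. Bulge identity genes (16 of 28 higher, median 1.02), quiescence genes (13 of 21, 0.57), hemidesmosome genes (15 of 19, 0.92), secreted matrix genes (18 of 29, 1.28), TGF-beta and YAP targets (9 of 15, 0.78) and immediate early genes (22 of 22, 1.16) were higher and held with an estimated correlation. Adjusted over the list alone, the counts were 17, 13, 15, 18, 11 and 22. Npnt (log2 4.15 ± 0.28), Tgfbi (3.64 ± 0.21), Klf4 (2.45 ± 0.18) and Cyr61 (2.05 ± 0.17) stood among them. WNT response (0.76), heat shock (0.54), upper hair follicle (0.36) and hair germ (0.48) were called higher, and S phase (-0.38), ribosome biogenesis (-0.10), oxidative phosphorylation (-0.22), cholesterol (-0.17) and interferon (-0.41) lower, without holding. Median and test differed in sign for epidermal differentiation (-0.08, or 0.03 with genes at their bounds), ribosomal proteins (0.07) and glycolysis (0.04), none called.

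Cluster 4 shared high Acta2 and Edn2 with cluster 2 but had less of all 22 immediate early genes. Atf3, a stress-induced transcription factor, averaged 188 ± 43.2 against 2028 ± 85.1 CPM (SD, n = 2 libraries), a log2 fold change of -3.28 ± 0.24 (SE), Zfp36 65.2 ± 42.6 against 585 ± 164 CPM (log2 -3.04 ± 0.23), and Jund 450 ± 12.4 against 1414 ± 42.1 CPM (log2 -1.59 ± 0.12). Edn2, an endothelin gene, averaged 328 ± 18.7 against 64.3 ± 2.19 CPM (log2 3.35 ± 0.16). Lgr5 averaged 203 ± 37.6 against 103 ± 13.7 CPM (log2 1.38 ± 0.15), and Krt14 changed by log2 -1.12 ± 0.22. With immediate early and heat shock genes left out of the clustering, Zfp36, Klk10 and Krt14 had values of 0.11, 0.51 and 0.37 in the matched cluster, which is another set of cells: its overlap with cluster 4 (Jaccard index) was only 0.315, and Scrg1, Nppc and Col17a1, leading genes of cluster 3, were among its leading genes. Dio3 (log2 3.64 ± 0.36), Cps1 (3.32 ± 0.37) and Dhrs9 (3.25 ± 0.30) were further increases. Ly6d was lower by a ratio of 187 (95% counting interval 33.5 to 7381), Aqp3 by 127 (22.8 to 5032) and Klf5 by 65.5 (18.1 to 541), and Klk10, at 0 UMIs, was at least 7.81-fold lower. Immediate early genes (22 of 22 lower, median -1.80), quiescence genes (10 of 21, -1.15), TGF-beta and YAP targets (6 of 15, -0.24) and epidermal differentiation genes (9 of 16, -2.01) were lower, and secreted matrix genes higher (15 of 29, 0.93), all holding with an estimated correlation. Adjusted over the list alone, the counts were 22, 12, 7, 9 and 16. Id3 (log2 -2.30 ± 0.22), Cdkn1a (-2.53 ± 0.25) and Smad7 (-2.66 ± 0.29) fell. S phase (0.90), hemidesmosome (0.25), actin (0.75) and oxidative phosphorylation (0.18) were called higher, and heat shock (-0.80), stratified keratins (-2.38), glycolysis (-0.25), cholesterol (-0.29), p53 targets (-0.27) and upper hair follicle (-4.06) lower, without holding. With genes at their bounds, the medians of quiescence, differentiation and upper follicle genes were -0.84, -1.43 and -2.28. Median and test differed in sign for WNT response (-0.55), hair germ (-0.01) and interferon response (0.14), none called.

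A direct comparison of clusters 2 and 4 gave 572 genes higher and 170 lower in cluster 2. Immediate early genes had a median log2 fold change of 2.01, with 21 of 22 higher (22 adjusted over the list alone) and an adjusted p = 0.00130 with an estimated correlation. Quiescence and BMP response genes were higher, 7 of 21 against 1 lower (the same adjusted over the list alone), with a median of 0.52 and an adjusted p = 0.0271 with an estimated correlation. The quiescence list shares Btg2 with the immediate early list, so these calls are not fully separate. Heat shock genes had a median of 0.84, with 8 of 14 higher (10 adjusted over the list alone), and did not hold. Secreted matrix and actin genes had medians of 0.02 and 0.10 and were not called. This comparison was chosen after the clusters were seen.

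Cluster 5 had the highest levels of Acta2, Tagln and Fgf5 and the lowest of Krt14 and Krt5 among the non-cycling clusters. Acta2 averaged 2459 ± 415 against 371 ± 61.0 CPM (SD, n = 2 libraries), a log2 fold change of 4.36 ± 0.23 (SE), and Tagln 6266 ± 188 against 937 ± 55.7 CPM (log2 4.49 ± 0.32). Fgf5, a growth factor known to end anagen, averaged 246 ± 27.2 against 21.8 ± 0.133 CPM (log2 5.61 ± 0.23). Krt14 averaged 1021 ± 111 against 5137 ± 457 CPM (log2 -2.03 ± 0.24) and Krt5 changed by log2 -1.27 ± 0.17. Mki67 averaged 11 ± 0.913 against 43.7 ± 11.4 CPM (log2 -1.47 ± 0.37). Fbln5 (log2 6.41 ± 0.32), Pid1 (6.16 ± 0.34) and Kcnk1 (6.12 ± 0.30) rose most. Sostdc1 changed by -4.64 ± 0.39, Capns2 was lower by a ratio of 132 (95% counting interval 45.1 to 640), and Tgm5, at 0 UMIs, was at least 28.8-fold lower. Actin genes (19 of 20, median 1.12), secreted matrix genes (17 of 29, 0.94) and TGF-beta and YAP targets (10 of 15, 0.89) were higher. Cholesterol synthesis genes (15 of 24, -1.10) and epidermal differentiation genes (6 of 16, -1.31) were lower, and these 5 of 9 called lists held with an estimated correlation. Adjusted over the list alone, the counts were 19, 18, 11, 16 and 6. Igfbp7 (log2 2.88 ± 0.10), Tpm1 (1.98 ± 0.12) and Idi1 (-1.92 ± 0.22) were among their leading genes. Hair germ (0.33) was called higher, and G2/M (-0.58), ribosomal proteins (-0.24) and upper hair follicle (-2.60) lower, without holding. Median and test differed in sign for bulge identity (0.02), p53 targets (0.14) and oxidative phosphorylation (0.02), none called.

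Cluster 9 had more Krt15, Cd34, Nfatc1, Foxc1, Grem1 and Krt24 than the other non-cycling clusters. Krt15 averaged 23456 ± 8088 against 4443 ± 447 CPM (SD, n = 2 libraries), a log2 fold change of 2.46 ± 0.13 (SE), and Cd34 340 ± 171 against 80.1 ± 3.98 CPM (log2 3.81 ± 0.25). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided, the adjusted p for Cd34 was 3.43e-12, higher in both libraries. Nfatc1, a regulator of quiescence in bulge stem cells, averaged 142 ± 21.5 against 14.5 ± 5.30 CPM (log2 5.85 ± 0.34), and Foxc1 113 ± 26.0 against 24.5 ± 9.11 CPM (log2 4.49 ± 0.36). For Cd34, Nfatc1 and Foxc1 the fitted values exceed the ratios of the levels, since low clusters pull down the reference, a mean of log levels. Krt24 changed by log2 9.39 ± 0.32, Tgm5 by 8.30 ± 0.30 and Grem1, a BMP antagonist, by 7.57 ± 0.26. Chat was higher by a ratio of 499.7 and Myoc by 765 (95% counting intervals 165 to 2474 and 256 to 3760), Aebp1 was lower by 117 (21 to 4635) and Ptger4 by 77.7 (13.9 to 3071), and Ggt1, at 0 UMIs, was at least 32.7-fold lower. Acta2 changed by log2 -5.07 ± 0.61 and Mki67 by -1.82 ± 0.56, or by 0.99 without centring within libraries, in a matched cluster that is another set of cells, led by Cst6, Defb6, Ly6d and Krt79, leading genes of cluster 12 (overlap with cluster 9 0.755, Jaccard index). Bulge identity genes (19 of 28, median 1.89), quiescence genes (6 of 21, 0.43) and epidermal differentiation genes (7 of 16, 1.15) were higher, and actin genes (15 of 20, -1.25) lower, all holding with an estimated correlation. Adjusted over the list alone, the counts were 20, 8, 7 and 15. Calml3 (log2 6.18 ± 0.19), Dmkn (4.78 ± 0.23) and Sbsn (3.24 ± 0.14) led the differentiation list. The bulge identity list holds all 15 markers by which the cluster was named, read in the same held-out UMIs. Nfatc1, Foxc1, Bmp6 and Fgf18 of these are also in the quiescence list. The calls of these lists therefore describe the cluster and add no independent support for its name. WNT (1.34), hedgehog (1.32), hemidesmosome (0.40), stratified keratins (0.62), glycolysis (0.45) and upper hair follicle (1.27) were called higher, and S phase (-1.29), G2/M (-1.86), heat shock (-0.06) and oxidative phosphorylation (-0.22) lower, without holding. Secreted matrix (-0.05, or 0 with genes at their bounds) and TGF-beta and YAP targets (-0.30) were called higher with medians not above 0, and ribosome biogenesis (0.05) and hair germ (-0.03) differed in sign without a call. With genes at their bounds, the S phase and G2/M medians were -0.97 and -1.01. Replicate 1 gave 44 cells of this cluster, so its values there rest on few cells.

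Cluster 12 had more Defb6, Cst6 and Krt79, genes of the upper follicle, more Krt77 and Krt10, and no detected Cd34 in the held-out UMIs. Cd34 averaged 137 ± 24.6 CPM in the other non-cycling clusters (SD, n = 2 libraries) and was at least 15.1-fold lower in cluster 12, as Fn1 was at least 15.5-fold and Cpxm1 at least 14.5-fold. Defb6, a defensin gene, averaged 2121 ± 1149 against 5.18 ± 5.96 CPM, a log2 fold change of 10.43 ± 0.24 (SE), and Cst6 4177 ± 3873 against 27.9 ± 4.77 CPM (log2 7.80 ± 0.24). Krt77 changed by log2 11.14 ± 0.37, Akr1c18 by 10.85 ± 0.43, Cidea by 9.43 ± 0.51 and Krt79 by 8.63 ± 0.39. Lgr5 averaged 16.1 ± 11.9 against 134 ± 21.9 CPM (log2 -3.12 ± 0.40), and Mki67 131 ± 66.2 against 23.7 ± 0.169 CPM (log2 2.57 ± 0.40). Upper hair follicle genes (8 of 9, median 4.56), epidermal differentiation genes (12 of 16, 2.35) and cholesterol and lipid synthesis genes (9 of 24, 0.65) were higher, and these 3 of 13 called lists held with an estimated correlation. Adjusted over the list alone, the counts were 8, 13 and 10. Scd1 (log2 5.20 ± 0.24), Krt10 (4.19 ± 0.28) and Elovl6 (2.60 ± 0.20) were among them. The cluster was named from the same 9 upper hair follicle genes in the same held-out UMIs. The call of that list therefore describes the cluster and adds no support for its name. G2/M (1.54), interferon (0.24), ribosomal protein (0.22) and ribosome biogenesis (0.46) lists were called higher, and bulge identity (-2.20), WNT (-1.47), hedgehog (-1.73), secreted matrix (-2.51), actin (-1.45) and hair germ (-1.34) lower, without holding. With genes at their bounds, the bulge, WNT, hedgehog, secreted matrix and actin medians were -0.68, -0.51, -1.18, -0.95 and -1.22. Median and test differed in sign for quiescence (-0.20), TGF-beta and YAP targets (-0.14), p53 targets (-0.12) and hemidesmosome genes (0.01), none called. The cluster rests on 58 cells.

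Cd34 was fitted as higher in clusters 2, 3 and 4 as well, by log2 2.03 ± 0.34, 1.72 ± 0.41 and 2.26 ± 0.33 (SE, n = 2 libraries), although its mean level was 126 ± 19.1, 107 ± 15.5 and 145 ± 8.55 CPM against 116 ± 27.8, 119 ± 22.0 and 113 ± 26.0 in the others. The reference is a mean of log levels, which cluster 12, at 0 held-out UMIs, lowers. Without cluster 12, the log2 fold change of Cd34 in cluster 3 was -0.0056. Krt15 was lower in cluster 3, by log2 -0.65 ± 0.16, while the clusters matched to it at a mitochondrial limit of 20% and at resolution 0.3 gave 1.61 and 1.66. Those clusters are other sets of cells, with overlaps (Jaccard index) of only 0.404 and 0.408 with cluster 3, and Calml3, Krt24 and Aqp3, leading genes of cluster 9, were among their leading genes.

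Clustered alone, replicate 1 gave 10 clusters and replicate 2 gave 9, and 7 pairs were each other's best match. Their correlation across variable genes had a median of 0.784 and a minimum of 0.496, and in 4 of the 7 pairs the commonest joint cluster was the same. By the commonest joint cluster, fibroblast-like cluster 11 (r = 0.906), cycling cluster 7 (r = 0.832) and Acta2-high cluster 5 (r = 0.882) were matched, the last by 664 cells of replicate 1, of which at most 281 can be from joint cluster 5. Cells of cycling cluster 8 in replicate 1 were matched to those of non-cycling cluster 1 in replicate 2 (r = 0.784). Cells of bulge stem cell-like cluster 9 in replicate 2 were matched to those of cluster 3 in replicate 1 (r = 0.603). By this label, clusters 1, 3, 6, 8, 9, 10 and 12 were not matched to themselves. Cluster 4 was the commonest joint cluster of no cluster in either library, so it was not found again by this label. In replicate 2 this also held at the other resolutions and numbers of variable genes. In replicate 1 it was the commonest of a cluster at resolution 0.8 and with 1000 or 4000 variable genes. Cells of cluster 6 in replicate 2 were matched to those of inner root sheath-like cluster 10 in replicate 1, at r = 0.496, the lowest value.

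Identifiers and positions (GRCm38) were as follows for the genes always named. Cd34 (ENSMUSG00000016494) is on chromosome 1 from 194938819 to 194961279, Krt14 (ENSMUSG00000045545) on chromosome 11 from 100203162 to 100207548, and Krt15 (ENSMUSG00000054146) on chromosome 11 from 100131758 to 100135928. Krt5 (ENSMUSG00000061527) is on chromosome 15 from 101707070 to 101712898, Lgr5 (ENSMUSG00000020140) on chromosome 10 from 115450311 to 115587780, and Mki67 (ENSMUSG00000031004) on chromosome 7 from 135689784 to 135716361. Col17a1 (ENSMUSG00000025064) is on chromosome 19 from 47646344 to 47692094 and Acta2 (ENSMUSG00000035783) on chromosome 19 from 34241090 to 34255590. All are annotated as protein coding.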

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

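All tests of clusters 2 and 4, the doublet test of cluster 6 and the matched-state test of ribosomal protein genes were chosen only after the result was seen, as were the comparison with the mean of clusters 2 and 4 and the naming of the genes here. The comparison of clusters 7 and 4 with clusters 8 and 1 was also chosen after the clusters were seen, and the barcodes left out were picked after their values were seen. Only the tests of cell loss and of shared library differences for cluster 6, and of scaling for ribosomal protein genes, were written down beforehand. Both libraries belong to 1 group, so no biological explanation was tested.

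The change from non-cycling to cycling cells differed between states in a test of the difference itself. By edgeR's quasi-likelihood test, 75 genes differed between the change from cluster 4 to cluster 7 and the change from cluster 1 to cluster 8, all of them with the higher value in the former. Nfkbia changed by log2 2.42 between clusters 4 and 7 and by -0.30 between clusters 1 and 8, Atf3 by 2.48 and -0.37, and Zfp36 by 1.99 and -0.61. With cluster 7 set against the mean of clusters 2 and 4, the test called 1 gene, Mt1 (log2 4.40, adjusted p = 0.0237), so the difference may rest on the choice of cluster 4 as the partner.

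That choice leads to the pattern weighed here, the difference in immediate early genes between clusters 2 and 4. Depth is argued against as the cause: the median UMIs of cluster 2 were at most 1.16 times those of cluster 4 in either library, and 1.12 times in the other. When immediate early and heat shock genes were left out of the clustering, 41.3% of the cells of cluster 4 (95% interval 37.4 to 45.2) joined the cluster that held most of cluster 2, which took 85.4% of the cells of cluster 2. The lists may therefore make part of the split. Whether they make all of it stays open, as does induction of these genes during tissue handling, which was not tested.

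Barcodes left out for their mitochondrial share were assigned to the cluster whose profile was closest. Of the 496 such barcodes of replicate 2, 27.6% (95% interval 23.7 to 31.8) were closest to the bulge stem cell-like cluster 9. The share was 12.7% among the kept cells of replicate 2. Of the same 496 barcodes, a further 23.8% were closest to cluster 6, against 17.6% of kept cells. In replicate 1, 2.67% of 1087 such barcodes were closest to cluster 9, against 3.46% of its kept cells. The assignment returned 83.2% and 82.2% of kept cells to their own cluster. Kept cells were assigned from the clustering part of their UMIs and left-out barcodes from all of theirs, so the shares are not measured alike. The assignment also put more kept cells at cluster 9 than clustering did. These were 12.7% against 8.63% in replicate 2 and 3.46% against 1.19% in replicate 1. This item was picked after its values were seen.

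Cluster 6, in which Krtdap, Dmkn and Sostdc1 were leading genes, held 19.3% of replicate 2 and 0.864% of replicate 1. Loss of these cells from replicate 1 to the mitochondrial limit is argued against, since 1.29% of the barcodes left out there (95% interval 0.706 to 2.15) were closest to cluster 6. Doublets that the scores can find are argued against as well. With calls kept, 4.61% of the 629 cells of the matching cluster were called (3.11 to 6.55), against 4.96% of all cells. The calls are a fixed top share by score and do not find doublets of like state, which stay open. Median depth in cluster 6 was 15517 UMIs, against 9748 and 9596 over the kept cells of replicates 1 and 2. Differences that all cells of the libraries share are argued against, since the 50 leading genes of cluster 6 had a median log2 ratio of replicate 2 over replicate 1 of -0.031 (interval -0.07 to 0.05) in the other clusters. What also stays open, untested, is a difference in the tissue, the animal or the sort, for which the labels give no field.

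Ribosomal protein genes such as Rpl5 and Rpl13 were lower in cycling cells. As a list they did not hold with an estimated correlation (adjusted p = 0.269). A different mix of states among cycling and non-cycling clusters is argued against, since the higher of the medians within matched states was -0.52 (interval -0.54 to -0.49). Scaling of abundant genes stays open: 86 genes matched on abundance had a median of -0.12 (interval -0.19 to -0.05), in the same direction and smaller than the ribosomal protein genes, whose quartiles were -0.70 and -0.54. Scaling may thus account for part of the decrease.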

How the results depend on the processing

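The settings without the mixed clusters, without cluster 9, without cluster 12, without immediate early and heat shock genes in the clustering, with mixed clusters counted as cycling and with matched clusters were chosen after seeing the data; the other settings were planned. No count of genes, list or share that moved has a tested cause unless one is named: the cause was not tested.

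Most values were counted as unchanged. A called result counts so where it kept its direction and its call. An uncalled result counts so where it stayed uncalled, whatever its sign. With a library left out, a value counts as unchanged within the SD between the libraries, as no p-value exists there. Of 6875 values for 385 pairs of a named gene and a comparison, 6127 were unchanged, 350 weaker, 74 stronger and 284 moved. In 40, a called gene changed sign. Of 792 values for gene lists, 661 were unchanged, 90 weaker, 14 stronger and 24 moved. In 3, a called list changed sign. Of 131 values for shares of clusters, 104 stayed within the SD between the libraries. Shares with a library left out always lie within it. The SD is also wide where the libraries differ, as in cluster 1 (9.94), so this count does not measure robustness. A cluster without a match in a setting gave no value there, as for cluster 4 in several settings. A matched cluster can be another set of cells: the overlap (Jaccard index) with cluster 3 was 0.404 at a mitochondrial limit of 20%, 0.408 at resolution 0.3 and 0.430 without immediate early and heat shock genes in the clustering, and with cluster 4 it was 0.315 in the last of these. The overlap with cluster 2 was 0.601 with all UMIs, 0.483 with doublets kept and 0.667 at a mitochondrial limit of 5%, and about as low with another split, with at least 500 genes and without centring; in none of these was a cluster matched to cluster 4. It was also low at resolutions 0.3 and 0.8 (0.581 at the latter), at a mitochondrial limit of 20% (0.688) and without immediate early and heat shock genes in the clustering (0.649). Without centring, the overlap with cluster 9 was 0.755 and none was matched to cluster 12. At resolution 0.3, none was matched to clusters 4, 8, 9, 10 and 12. Values below for these clusters and settings are therefore not those of the same set of cells.

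The fit with no replicate block called 467 genes lower in cluster 1, 707 higher and 231 lower in cluster 2, 916 higher and 162 lower in cluster 3, 808 higher and 560 lower in cluster 4, and 5 lists between cycling and non-cycling cells. DESeq2 called 381 genes lower in cluster 12. An estimated correlation left 1 list called for cycling cells and 32 for the clusters, and fry called 16 for cycling cells. It asks another question, whether a list moves at all.

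With all UMIs, so that the same counts formed and tested the clusters, 883, 761, 1347 and 1342 genes were lower in clusters 2, 3, 5 and 9, and other cell types made up 2.14%. The medians of epidermal differentiation in cluster 1, immediate early genes in cluster 2 and heat shock in cluster 2 became -0.017, -0.024 and -0.083, and Hspb1 in cluster 2 became -0.095. Hspb1 also changed sign with another split (-0.14), a mitochondrial limit of 5% (-0.23), at least 500 genes (-0.00055), doublets kept (-0.30) and no centring (-0.087).

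At a mitochondrial limit of 5%, 3057 genes differed jointly, 471 were higher in cluster 2 and 677 lower in cluster 3, other types made up 3.64%, Rps12 in cluster 1 became 0.14 and Krt15 in cluster 2 became 0.26. At 20%, 151 genes were lower in cluster 2 and other types made up 1.88%. Cdk1 in cluster 1 became -0.061, Krt14 in cluster 2 0.055, Rplp0 in cluster 5 0.026, and in cluster 3 Calm4 became 5.10, Nop16 0.29, Fdps 0.31, Idi1 0.26, Scd1 0.053 and Krt15 1.61. With at least 500 genes per cell, other types made up 3.0%. With at least 2000, 828 genes were higher in cluster 4 and Rps12 in cluster 1 became 0.043. With doublets kept, Jund in cluster 2 became -0.0058.

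At resolution 0.3, 1169 genes were lower in cluster 1, 524 higher and 244 lower in cluster 2, and 1203 lower in cluster 3. Calm4 and Aqp3 in cycling cells became 0.90 and 0.50, Cks2 and Hk1 in cluster 2 became -0.092 and 0.025, and in cluster 3 Calm4 became 7.68, Id4 -0.29, Nop16 0.38, Fdps 0.50, Idi1 0.82, Scd1 2.52, B2m 0.16, Psmb8 0.98 and Krt15 1.66. At resolution 0.8, 292 genes were lower in cluster 2. Without centring within libraries, 621 and 1352 genes were lower in clusters 3 and 5, and Mki67 in cluster 9 became 0.99.

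Without cluster 9, 306 and 693 genes were lower in clusters 2 and 3. Without cluster 12, Cd34 in cluster 3 became -0.0056, because cluster 12 has 0 Cd34 UMIs in the held-out part. With immediate early and heat shock genes left out of the clustering, 999 genes were lower in cluster 3 and 458 in cluster 4, and in cluster 4 Cyr61 became 0.92, Zfp36 0.11, Klk10 0.51, Krt14 0.37 and Krt5 0.12.

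For cycling cells, 679 genes were higher and 634 lower when cell cycle genes were left out of the clustering and cells were called by markers. Cluster 7 against cluster 4 gave 558 and 393, and cluster 8 against cluster 1 gave 473 and 246. The test of the difference between states called 1 gene with the mean of clusters 2 and 4. The share of cycling cells was 24.1% with mixed clusters counted as cycling, 35.5% by markers and 27.7% by markers after thinning. With mixed clusters counted as cycling, replicate 2 had the higher share. Unthinned, Cd34 was detected in 46.1% of keratinocytes, since depth sets detection.

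Leaving out each library gave cycling shares from 7.97% to 16.2%, shares of other types from 1.92% to 2.05%, shares of cluster 6 from 0.864% to 19.3% and of cluster 9 from 1.19% to 8.63%, and Cd34 detection from 29.1% to 33.0%. Rpl32 in cluster 12 had a log2 fold change of -0.018 without replicate 2 and 0.80 without replicate 1. A fit on 1 library has no spread between libraries, so no count of genes was made.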

Other observations

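None of the values here belongs to a planned comparison, and all of these items were chosen after the result was seen.

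Between the libraries, 5 genes were lower and 5 higher in replicate 2 by more than log2 1 in all 6 clusters with at least 100 cells in each library, with 10 CPM added to each level and no other limit on the level. Lower were Gm10320 (median log2 ratio -3.52), Slpi (-1.68), Gm8797 (-1.58), Rpl27 (-1.39) and Zrsr1 (-1.23). Higher were Gstp1 (1.66), mt-Nd4l (1.42) and Rpl35 (1.11), with Gm10260 and Ccdc85b between these. Several of these share sequence with pseudogenes or paralogs, so their counts are uncertain. The total counts of the libraries had r = 0.984 across 15152 genes.

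Xist was detected in 3 cells of replicate 1 (0.0810%) and 8 of replicate 2 (0.275%), and a Y-linked gene in 71.8% and 68.1% of cells. Both libraries thus had the same pattern, that of cells from males. The sorted libraries shared 11 barcode sequences.

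Among the doublet calls that had passed the other filters, 13.7% of 131 in replicate 2 (95% interval 8.35 to 20.8) were closest to the inner root sheath-like cluster 10. In replicate 1 it was 2.34% of 214 (0.763 to 5.37). Of the kept cells it was 2.41% in replicate 2 and 2.27% in replicate 1, so that replicate 1 shows no excess. Kept cells were assigned from the clustering part of their UMIs and the doublet calls from all of theirs. The cells kept in cluster 10 had the greatest median depth, 19180.5 UMIs, and a median doublet score of 0.0639.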
